A study of Neochloris aquatica with 8 samples.

How the data were processed

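The series holds 8 libraries of poly(A)-selected RNA from the green alga Neochloris aquatica, 2 at each of 4 nitrate concentrations (3, 9, 18 and 27 mmol/L). RNA was extracted with TRIzol and enriched on magnetic poly(A) beads, per the labels' protocols. Reads were processed with Trimmomatic 0.35 and Bowtie (version not given in the sources used here), per the submitters' processing notes, and the transcriptome was assembled de novo, per the series design. The gene identifiers have the form that the assembler Trinity writes. The assembly itself was not used here, so genes are named by their identifiers and have no genomic position.

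The deposited expression table gives 1 value per assembled gene and library. Its name says that the authors scaled libraries by TMM (trimmed mean of M values). That the deposited values are FPKM (fragments scaled by transcript length and library size) is inferred from the values: library sums lie between 16314622 and 22613856, and the value of 1 fragment falls with transcript length. The estimator of abundance is not given in the sources used here. No identifier had an isoform suffix, so no rows were summed. A deposited annotation file lists conserved-domain hits found with rpstblastn on the assembled transcripts, and its score column is an E-value of at most 1e-05, per the file. It held 296103 hits on 20965 genes, of which 15796 had a hit at an E-value of 1e-10 or less. The file gives no alignment score, so equal E-values were left in file order.

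The file gives no read totals, so the depth in reads is unknown. Relative depth was read from genes with transcripts of 205 to 340 bp, whose low values sit on whole multiples of the value of 1 fragment. Between 89.9% and 96.1% of the low values tested per library lay within 0.1 of a whole multiple. At 300 bp, 1 fragment was worth between 7.57 and 10.93 FPKM, and values of that size rest on single fragments.

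Values were analysed as log2(FPKM + 1), and fold changes are on that scale, which understates the change of low genes. Genes with a mean of at least 1 over the 8 libraries were tested with limma 3.58.1 in R 4.3.3. One fit held the 4 groups, with no replicate block, a trended prior variance and 4 residual degrees of freedom. The comparisons were 3 against 18, 9 against 18, 27 against 18 and 3 against 27 mmol/L. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 in Python 3.11.15.

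Lists of genes for 26 pathways and marker groups were fixed as text patterns before the data were examined. A gene joined a list when 1 of the 3 best domain hits of a transcript, at an E-value of 1e-10 or less, matched in accession, name or description. Such matching takes in genes that only share words with the list, and these are named where they matter. Of these lists, 4 hold markers of other organisms that an algal culture can carry (bacteria, animals, fungi, and retroelements and viruses). Each list was tested with camera from limma at a preset correlation of 0.01, adjusted over the 26 lists, and again with an estimated correlation and with fry. Genes were named by a rule fixed before the data were examined: up to 5 rises and 5 falls among called genes with a domain, the gene with the smallest p in each list, and the best expressed match for each of a set of core enzymes and transporters. The first part named none, since no gene was called. Genes named outside the rule are said to have been chosen after their values were seen.

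The fit was tested on simulated data, 10 times per setting, with 200 genes changed by log2 1, 2, 4 or 6. A first version of the simulation used the moderated gene variances as the true ones, which narrows their spread. A second version, written after its result was seen, drew the variances from the fitted prior. Both are given. For 3 against 18 mmol/L over 123022 genes, 18% of calls were false with moderated variances and 13% with drawn variances, above the nominal 5%. Over the 24485 genes with a mean of at least 50 the shares were 8.2% and 6%. With drawn variances, limma recovered 0%, 0.8%, 22.8% and 71.8% of changes of log2 1, 2, 4 and 6 over 123022 genes. Over the 24485 genes it recovered 0%, 1.6%, 45.6% and 75.8%. For 3 mmol/L against the 6 other libraries, over 24485 genes, 5.6% and 4.9% of calls were false with moderated and drawn variances. With drawn variances 0.2%, 15.2%, 78.4% and 88.2% of the changes were recovered. Over 123022 genes, 18% and 21% of the calls of this comparison were false. A shifted flagella list was called in 10 of 10 simulations. Among the other 25 lists there was 1 call over the 10 simulations with moderated variances and 0 with drawn variances. Genes were drawn independently of each other, so these list results do not cover lists of correlated genes. In the data the estimated correlation within lists ranged from 0.05 (fungal markers) to 0.24 (flagella).

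Alternatives covered the pseudocount, the filter on low values, rescaling and centring of libraries, the prior variance, a replicate block, the matching of lists and leaving out each library. Alternatives with a mean of at least 50 and a pseudocount of 10 were added after the data were seen. So were title-only list matching, the restriction to genes with a domain hit, and leaving out the 3 libraries richest in prokaryote-type transcripts (3 mmol/L replicate 2, 18 mmol/L replicate 1 and 27 mmol/L replicate 1). The comparison of 3 mmol/L with the 6 other libraries was also added then. A check of transcript length was set aside, since only 2632 of the 24485 genes have a length. On these, the log2 difference between libraries correlated with length at -0.17 to 0.19 over the pairs. Between 18 mmol/L replicate 1 and 27 mmol/L replicate 1 the correlation was 0.19.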

Results

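Transcripts of Neochloris aquatica, a unicellular green alga, were measured in logarithmic growth at 4 nitrate concentrations. BG11 medium with 18 mmol/L nitrate was the control, 3 and 9 mmol/L were lower and 27 mmol/L was higher. The study addressed how scarce and abundant nitrogen change the transcriptome. Each concentration had 2 libraries, replicates 1 and 2. The labels do not say whether these were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Relative depth ranged from 0.693 in 9 mmol/L replicate 2 to 1.0 in 18 mmol/L replicate 1. Between 31.5% (27 mmol/L replicate 1) and 50% (3 mmol/L replicate 1) of the assembled genes were listed at 0 in a library. Values are TMM-scaled FPKM, and n = 2 libraries per group except where libraries are left out.

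Genes whose best domain model is of prokaryote type were unevenly spread over the libraries. Of 2453 such genes with a mean between 1 and 50, 73% were above 0 in 3 mmol/L replicate 2 and 69.8% in 27 mmol/L replicate 1. The share was 36.5% in 18 mmol/L replicate 1 and between 11.4% and 17.9% in the other 5 libraries. Plant-type genes at the same level were above 0 in 68.8% to 86%. These low-level prokaryote-type genes held at most 0.14% of the summed FPKM of a library. Libraries of 1 concentration were not the most alike. Over 24485 genes with a mean of at least 50, the log2 difference within a pair of replicates had an SD of 1.61 at 3 mmol/L, 1.39 at 9 mmol/L, 1.40 at 18 mmol/L and 1.39 at 27 mmol/L. Between 18 mmol/L replicate 1 and 27 mmol/L replicate 1 the SD was 0.84.

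**Figure D1:**
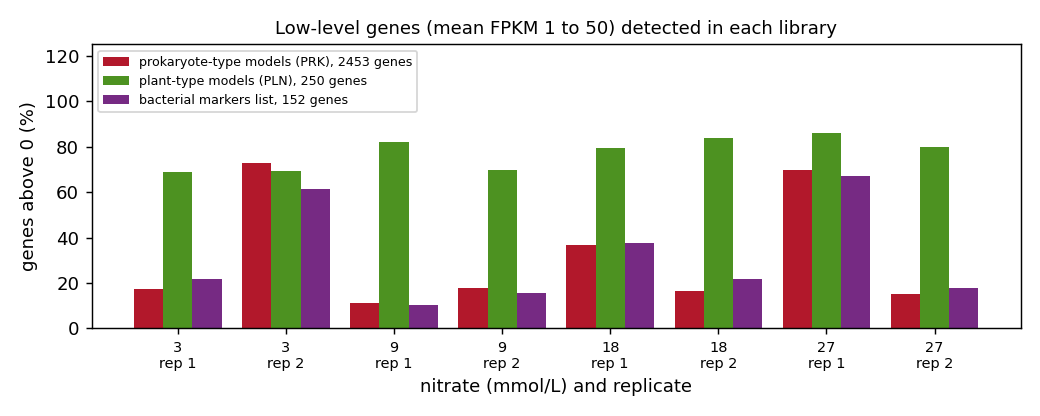
Percent of low-level genes (mean FPKM 1 to 50) above 0 in each of the 8 libraries, by nitrate concentration and replicate. Bars give prokaryote-type genes (2453), plant-type genes (250) and genes of the bacterial marker list (152). Prokaryote-type genes reach 73% in 3 mmol/L replicate 2 and 69.8% in 27 mmol/L replicate 1.

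In the comparison of 3 with 18 mmol/L, cytosolic ribosomal protein genes rose as a group and flagella genes fell. Of 147 ribosomal genes, 101 were higher and 45 lower at 3 mmol/L, with a median log2 difference of 0.35 (camera adjusted p = 1.93e-07, and 0.997 with an estimated correlation). Of 79 flagella genes, 67 were lower, with a median of -0.79 (adjusted p = 0.000744, and 0.997 with an estimated correlation). The mean of the ribosomal list was 0.14, and with a mean FPKM of at least 50 the flagella list (38 genes, median -0.53) was not called, at an adjusted p of 0.737. The median over all tested genes was -0.17, so the ribosomal rise is larger against it and the flagella fall smaller. The member of the ribosomal list with the smallest p was TRINITY_DN54853_c0_g1, a RIO1 kinase, known for its role in maturing the small ribosomal subunit. It had 11.5 ± 11.4 FPKM at 3 mmol/L and 79.0 ± 28.9 (SD) at 18 mmol/L, a difference opposite in sign to the list (limma adjusted p = 0.53). In the flagella list it was TRINITY_DN60514_c0_g2, a monogalactosyldiacylglycerol synthase, which makes a chloroplast galactolipid, with 86.7 ± 61.7 and 286 ± 90.2 FPKM (adjusted p = 0.56).

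Genes of glycolysis and the tricarboxylic acid cycle, amino acid synthesis, and chlorophyll and haem synthesis also rose as lists at 3 mmol/L, with medians of 0.48 (326 genes, adjusted p = 0.000133), 0.44 (404 genes, adjusted p = 0.00149) and 0.47 (159 genes, adjusted p = 0.00388). The adjusted p was 0.997 for each with an estimated correlation. Low-level members of these lists were spread over libraries like the prokaryote-type transcripts. Of 234 in the glycolysis list, 76.1% were above 0 in 3 mmol/L replicate 2, 18.4% in 3 mmol/L replicate 1, and 36.3% and 14.1% in the control libraries. The corresponding shares were 78.2%, 21.8%, 38.6% and 16.4% of 280 amino acid synthesis genes, and 83.9%, 23%, 34.5% and 14.9% of 87 chlorophyll and haem genes. Among members with a mean of at least 50, the medians were -0.31, -0.32 and -0.29, near the -0.35 of all genes at that level, and none of the 3 lists was called. At that level without the 3 libraries richest in prokaryote-type transcripts the medians were -0.507, -0.593 and 0.167, and the chlorophyll and haem list was called up (adjusted p = 0.0271, not run with an estimated correlation). That fit compares 1 library with 1, and its spread comes from the 9 mmol/L pair alone. In the glycolysis and amino acid lists, the gene with the smallest p was TRINITY_DN82130_c0_g1, an isopropylmalate isomerase of prokaryote type, at 35.3 and 47.8 FPKM at 3 mmol/L and listed at 0 in the other 6 libraries.

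Among single genes, a fasciclin-domain gene (TRINITY_DN54663_c0_g1), of a family of cell adhesion proteins, had 682 ± 287 FPKM at 3 mmol/L and 8810 ± 1130 at 18 mmol/L, a log2 difference of -3.75 ± 0.51 (SE). An expansin A gene (TRINITY_DN61315_c1_g1), named for proteins that loosen plant cell walls, had 7870 ± 3110 and 36400 ± 4320 FPKM. A glycosyl hydrolase of family 1 (TRINITY_DN57984_c0_g1) had 385 ± 87.6 and 1490 ± 67.7, and an omega-3 fatty acid desaturase (TRINITY_DN58767_c7_g2), which adds a double bond to polyunsaturated fatty acids, 385 ± 204 and 1470 ± 339. These 4 genes were chosen after their values were seen, and limma gave them adjusted p of 0.48, 0.52, 0.52 and 0.52. By the fixed rule, a RuBisCO activase gene (TRINITY_DN62377_c7_g1), which keeps the carbon-fixing enzyme active, had 222 and 511 FPKM in the 3 mmol/L libraries and 1080 and 2840 in the control. A beta-carotene ketolase (TRINITY_DN59544_c0_g1), an enzyme of astaxanthin synthesis, had 258 ± 149 and 1870 ± 1510. A glutathione peroxidase (TRINITY_DN56072_c0_g2) had 35.8 ± 16.6 and 218 ± 38.8, a copper-type nitrite reductase (TRINITY_DN59256_c1_g1) 11.0 ± 6.11 and 100 ± 18.5, and a light-harvesting chlorophyll a/b protein (TRINITY_DN57983_c5_g8) 4140 ± 308 and 13400 ± 2250. A histone H2A gene (TRINITY_DN46708_c0_g1) had 48.0 ± 27.0 and 272 ± 103, and a glycosyl hydrolase of family 31 in the starch list (TRINITY_DN62278_c1_g2) 21.1 ± 5.93 and 179 ± 4.99. Each of these 7 had an adjusted p of 0.52.

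**Figure D2:**
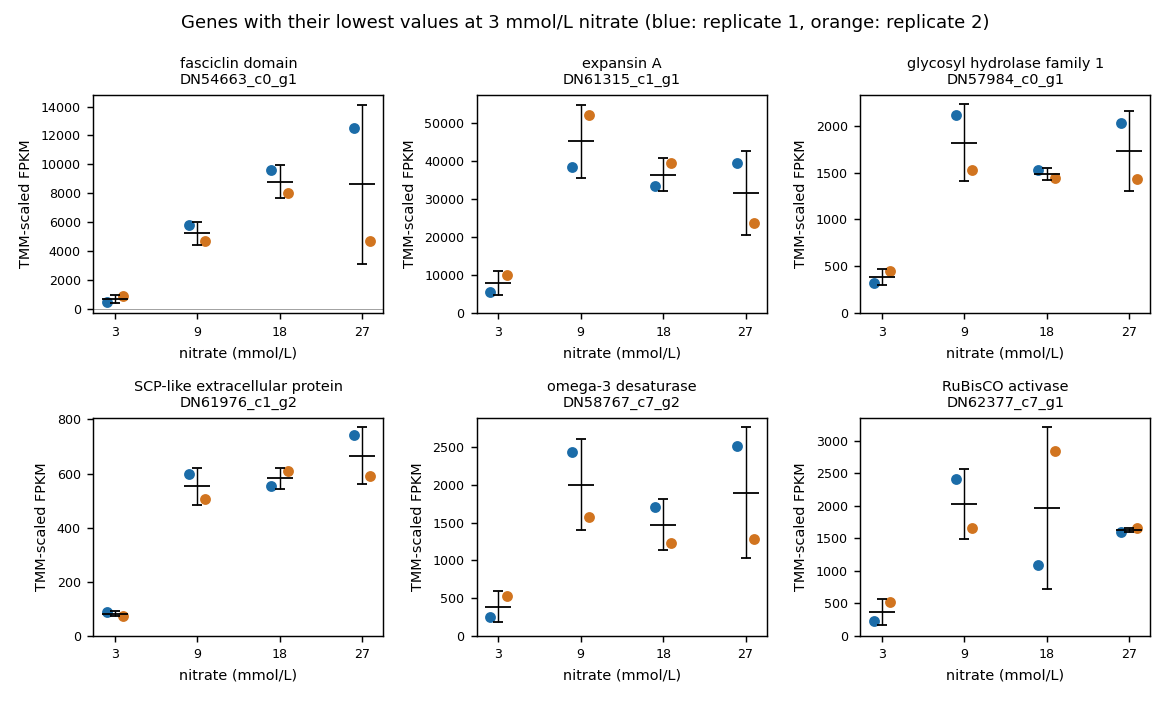
TMM-scaled FPKM of 6 genes in each library against nitrate concentration (mmol/L), on linear axes. Blue points are replicate 1, orange points replicate 2, and the horizontal dash with its bar is the mean ± SD of 2 libraries. The fasciclin gene lies at 480 and 885 FPKM at 3 mmol/L and between 4670 and 12500 in the other libraries.

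Core genes of nitrogen use were not called. The best expressed ammonium transporter (TRINITY_DN59747_c0_g1) had 7060 ± 7070 FPKM at 3 mmol/L and 3890 ± 1790 at 18 mmol/L, and glutamine synthetase (TRINITY_DN61803_c1_g1), which joins ammonium to glutamate, 1900 ± 790 and 3140 ± 377. NAR2, an accessory protein of high-affinity nitrate uptake (TRINITY_DN58014_c0_g1), had 1170 ± 1490 and 1290 ± 582. The best expressed match for nitrate reductase was a gene with a cytochrome b5 domain only (TRINITY_DN60188_c0_g1), with 1920 ± 281 and 1210 ± 1270, and that for nitrite reductase was a Rieske-domain gene (TRINITY_DN60689_c5_g1), with 1080 ± 645 and 1470 ± 601. A gene with an NADPH nitrate reductase model (TRINITY_DN60985_c2_g1), chosen after its values were seen, had 4.92 and 255 FPKM in the 3 mmol/L libraries and 120 and 746 in the control. A second gene with that model (TRINITY_DN62837_c1_g2), also chosen after its values were seen, had 8.06 and 8.79 FPKM against 116 and 178, a log2 difference of -3.94 ± 0.91 (limma adjusted p = 0.52). Also chosen after their values were seen, a nitrate transporter (TRINITY_DN59633_c2_g1) had 167 and 1150 FPKM at 3 mmol/L and 354 and 833 in the control, and a ferredoxin-nitrite reductase (TRINITY_DN59962_c0_g1) 67.2 and 606 against 210 and 721. The match for glutamate synthase was a tetrahydrofolylpolyglutamate synthase (TRINITY_DN61676_c5_g1), a folate enzyme, at 7790 ± 5120 and 6440 ± 1890. Among lipid and carbon genes, diacylglycerol acyltransferase (TRINITY_DN62769_c3_g1), which makes storage triacylglycerol, had 3390 ± 1710 and 2050 ± 1180. Acetyl-CoA carboxylase biotin carboxylase (TRINITY_DN59511_c0_g1) had 2860 ± 1330 and 4410 ± 287, acyl-ACP desaturase (TRINITY_DN59279_c0_g1) 3990 ± 4940 and 4090 ± 584, and the RuBisCO small subunit (TRINITY_DN52024_c3_g1) 361000 ± 42000 and 354000 ± 86600. The adjusted p of the genes of this paragraph lay between 0.75 and 1, apart from that of TRINITY_DN62837_c1_g2. The nitrogen list (222 genes) had a median of 0.0 and an adjusted p of 0.278, the fatty acid synthesis list (158 genes) a median of 0.0 and an adjusted p of 0.0876, and the triacylglycerol and membrane glycerolipid list (62 genes) a median of -0.07 and an adjusted p of 0.828. Among members with a mean of at least 50, these medians were -0.61 (67 genes, camera adjusted p = 0.565), -0.35 and -0.33. The median over all genes at that level was -0.35. Of 155 low-level nitrogen genes, 62.6% were above 0 in 3 mmol/L replicate 2, 22.6% in 3 mmol/L replicate 1, and 38.7% and 23.2% in the control libraries.

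**Figure D3:**
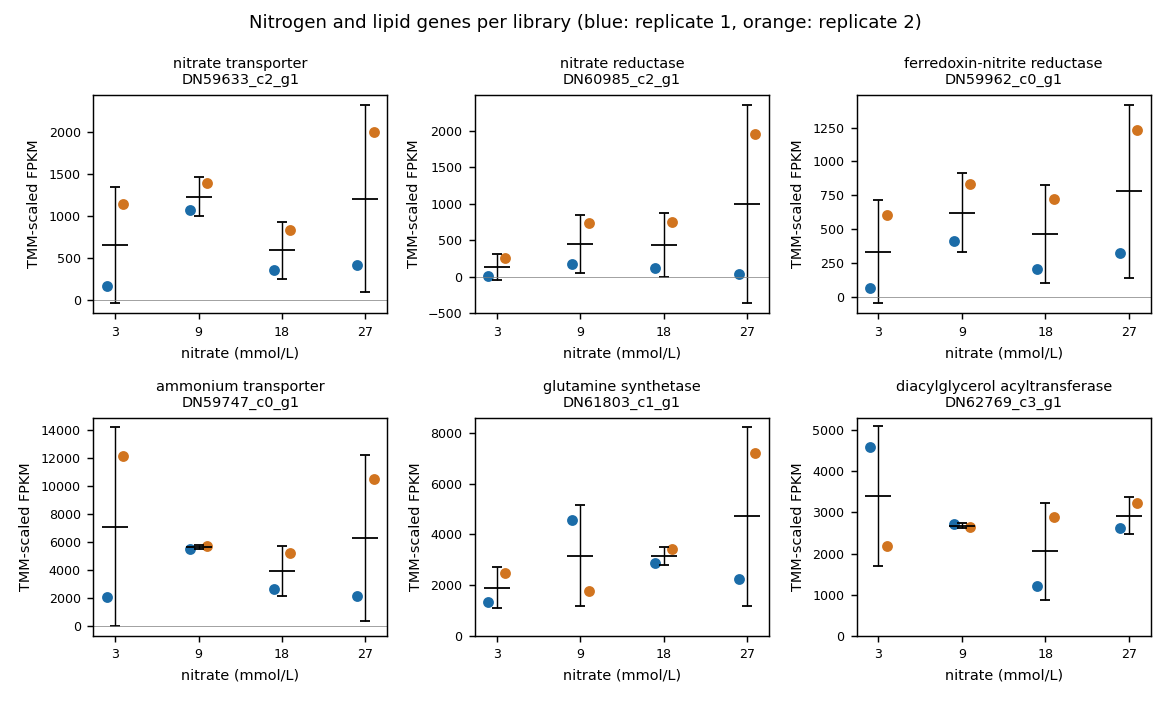
TMM-scaled FPKM of 6 nitrogen and lipid genes in each library against nitrate concentration (mmol/L), on linear axes. Blue points are replicate 1, orange points replicate 2, and the dash with its bar is the mean ± SD of 2 libraries. The ammonium transporter spans 2070 to 12100 FPKM within the 3 mmol/L pair.

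Over all genes, limma called 0 of 123022 between 3 and 18 mmol/L, with 9573 at an unadjusted p under 0.05 (2402 higher, 7171 lower) against 6151 from chance. Adjusted over the list alone, 0 genes passed in any of the 26 lists, and fry called 0 lists. A robust prior variance called 43 genes. Leaving out 3 mmol/L replicate 1 or 18 mmol/L replicate 1 gave 2553 and 2546 genes, of which 2426 and 2423 had a residual SD of 0. Instead of 5 lists, 8 were called without 3 mmol/L replicate 1, 3 without 3 mmol/L replicate 2 and 1 without 18 mmol/L replicate 2. Without 3 mmol/L replicate 2 and without 18 mmol/L replicate 2, the calls ended for flagella (medians -0.55 and -0.45), glycolysis (0 and 0.31), amino acid synthesis (0 and 0.07) and chlorophyll and haem (0 and 0.17). Without the 3 libraries richest in prokaryote-type transcripts, again 1 library against 1, the ribosomal list was the 1 list called (median 0.18), with medians of -0.952 for flagella, -0.041 for glycolysis, -0.242 for amino acid synthesis and 0 for chlorophyll and haem. Without 3 mmol/L replicate 2 the ribosomal median was 0.17. Without 3 mmol/L replicate 1 the medians of the flagella, amino acid and glycolysis lists were -1.215, 0.982 and 1.413, and without 18 mmol/L replicate 1 that of glycolysis was 1.211. Centring the libraries called 12 lists, 11 up and 1 down. It moved the medians to -0.156 for flagella, 0.981 for ribosomal genes and 1.113 for glycolysis. Those of amino acid synthesis and of chlorophyll and haem became 1.079 and 1.109.

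At 9 mmol/L, light-harvesting protein genes fell as a group against the control. These proteins bind chlorophyll and carry light energy to the photosystems. Of 71 genes, 56 were lower, with a median log2 difference of -0.68 (camera adjusted p = 0.00323), and the adjusted p was 0.993 with an estimated correlation. Highly expressed members (TRINITY_DN57983_c5_g1 and TRINITY_DN57983_c5_g3, chosen after their values were seen) had 167000 ± 139000 and 84800 ± 107000 FPKM at 9 mmol/L. In the control they had 406000 ± 261000 and 201000 ± 220000, and the adjusted p of each was 0.92. TRINITY_DN42294_c0_g1, the member with the smallest p, was at 61.6 and 44.0 FPKM in the control and listed at 0 in both 9 mmol/L libraries. Genes of photosystem and electron transport subunits had a median of -0.27 (160 genes, adjusted p = 0.222) and flagella genes -0.41 (79 genes, adjusted p = 0.0983). With a mean of at least 50, both were called, at adjusted p of 0.0159 and 0.0143, and at 0.996 with an estimated correlation neither was.

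Adjusted over the list alone, 1 gene passed at 9 mmol/L, a CHY zinc finger gene (TRINITY_DN60516_c1_g2) in the list for DNA replication and cell cycle (adjusted p = 0.0024 over the list, 0.46 over all genes in limma). It was at 155 and 154 FPKM in the control and listed at 0 in both 9 mmol/L libraries. Its neighbour in the same assembled component, TRINITY_DN60516_c1_g1, with the same domain, had 140 and 109 FPKM at 9 mmol/L and was listed at 0 in the control. Genes of the fixed rule with smaller differences were a lecithin cholesterol acyltransferase-domain gene (TRINITY_DN59232_c0_g2), at 468 ± 3.75 FPKM at 9 mmol/L and 212 ± 3.51 in the control, and a histone H3 gene (TRINITY_DN55613_c0_g5), at 131 ± 57.5 and 31.6 ± 26.0. Their adjusted p was 0.92. A lytic polysaccharide mono-oxygenase-domain gene (TRINITY_DN56083_c0_g1), of a family that cleaves cellulose, had 11000 ± 3000 and 705 ± 505 FPKM (adjusted p = 0.85, chosen after its values were seen). Ammonium transporter TRINITY_DN59747_c0_g1 had 5600 ± 147 and 3890 ± 1790, and glutamine synthetase TRINITY_DN61803_c1_g1 3160 ± 1980 and 3140 ± 377, at adjusted p of 0.98 and 1.

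Over all genes, limma called 0 of 123022 between 9 and 18 mmol/L, with 5602 at an unadjusted p under 0.05 against 6151 from chance. Among the 24485 genes with a mean of at least 50, 546 had such a p, against 1224 from chance. Within the 9 and 18 mmol/L pairs the SDs of the log2 difference were 1.39 and 1.4. The 0 therefore does not show that these groups are alike. A robust prior variance called 4 genes, and leaving out 18 mmol/L replicate 1 gave 2472, of which 2423 had a residual SD of 0. The light-harvesting call was lost without 9 mmol/L replicate 1 (median -0.33), without 18 mmol/L replicate 2 (-0.19) and without either 27 mmol/L library (-0.68). Without either 3 mmol/L library or 18 mmol/L replicate 1, 2 lists were called, and 0 without the 3 libraries richest in prokaryote-type transcripts (light-harvesting median -0.99, with 1 control library left). With a mean of at least 50 the light-harvesting list was called (median -0.75, camera adjusted p = 5.27e-05, and 0.996 with an estimated correlation). Without the 3 libraries as well, its median was -1.071. That fit has 1 control library and takes its spread from the 9 mmol/L pair alone. Fry called 0 lists.

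At 27 mmol/L, cytosolic ribosomal protein genes rose as a group against the control, 121 of 147 being higher, with a median log2 difference of 0.20 (camera adjusted p = 0.00621, and 0.921 with an estimated correlation). Genes of nitrogen uptake and assimilation (222 genes, median 0.33), glycolysis and the tricarboxylic acid cycle (326 genes, 0.22) and amino acid synthesis (404 genes, 0.23) also rose, each at an adjusted p of 0.0477. With an estimated correlation the adjusted p of these 3 lists was also 0.921. Low-level members were again spread like the prokaryote-type transcripts. Of 155 in the nitrogen list, 75.5% were above 0 in 27 mmol/L replicate 1 and 25.8% in replicate 2, against 38.7% and 23.2% in the control. For the glycolysis list the shares were 71.4%, 14.5%, 36.3% and 14.1%, and for amino acid synthesis 76.1%, 13.6%, 38.6% and 16.4%. With a mean of at least 50, the medians of these 3 lists were 0.15, 0.14 and 0.15 and none was called, while the ribosomal list was, at an adjusted p of 0.000498 (0.994 with an estimated correlation). Of 22 low-level ribosomal genes, 86.4% were above 0 in 27 mmol/L replicate 1 and between 50% and 54.5% in the other library and the control.

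The gene with the smallest p in each called list was listed at 0 in both libraries of 1 group. In the ribosomal list, a 40S ribosomal protein S23 gene (TRINITY_DN7640_c0_g1) had 353 and 24.5 FPKM at 27 mmol/L and was listed at 0 in the control. In the amino acid list, a persulfide dioxygenase-type gene (TRINITY_DN93254_c0_g1) had 20.5 and 27.0 FPKM in the control and was listed at 0 at 27 mmol/L. A 3-oxoacid CoA-transferase fragment (TRINITY_DN72557_c0_g1) had 35.4 and 15.9 FPKM at 27 mmol/L and was listed at 0 in the control, and a NirB nitrite reductase fragment of bacterial type (TRINITY_DN88326_c0_g1) had 30.9 and 21.7 FPKM in the control and was listed at 0 at 27 mmol/L. Among better expressed genes, chosen after their values were seen, a sugar transporter (TRINITY_DN57499_c0_g1) had 2030 ± 252 and 918 ± 43.2 FPKM. An ERp46-type protein disulfide isomerase (TRINITY_DN50060_c0_g1), which folds secreted proteins, had 1690 ± 355 and 494 ± 344. By the fixed rule, light-harvesting-like protein 3 (TRINITY_DN53702_c0_g1) had 3360 ± 90.1 and 2390 ± 34.5. Glutamine synthetase TRINITY_DN61803_c1_g1 had 4720 ± 3530 and 3140 ± 377, diacylglycerol acyltransferase TRINITY_DN62769_c3_g1 2930 ± 445 and 2050 ± 1180, and acetyl-CoA carboxylase TRINITY_DN59511_c0_g1 5370 ± 171 and 4410 ± 287. The adjusted p was 1 for each of these.

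Over all genes, limma called 0 of 123022 between 27 and 18 mmol/L, with 4018 at an unadjusted p under 0.05 against 6151 from chance, and 0 passed adjusted over the list alone. Among the 24485 genes with a mean of at least 50, 119 had such a p, against 1224 from chance. Across these groups, libraries of the same replicate number had SDs of the log2 difference of 0.84 and 1.05. Within the labelled pairs the SDs were 1.4 and 1.39, which widens the residual spread. The 0 therefore does not show that the groups are alike. A robust prior variance called 1 gene. Leaving out 18 mmol/L replicate 1 or 27 mmol/L replicate 2 gave 2451 and 4170, of which 2423 and 3488 had a residual SD of 0. Instead of 4 lists, 1 was called without 27 mmol/L replicate 1 or without either 9 mmol/L library, 0 without 18 mmol/L replicate 2 and 0 with centred libraries. Without either 3 mmol/L library 7 were called. The ribosomal call was lost without 18 mmol/L replicate 2 (median 0.21) or 27 mmol/L replicate 2 (0.14). The medians of the nitrogen, glycolysis and amino acid lists were 0 without 27 mmol/L replicate 1 and 0 without the 3 libraries richest in prokaryote-type transcripts (1 library against 1), and uncalled in both. Without 18 mmol/L replicate 2 the nitrogen and glycolysis medians were 0.551 and 0.382, uncalled. Without 27 mmol/L replicate 2 the glycolysis and amino acid medians were 0.709 and 0.528, and without 18 mmol/L replicate 1 that of glycolysis was 0.379. Fry called 0 lists.

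Between 3 and 27 mmol/L, the lowest and highest nitrate, flagella genes and genes of fatty acid desaturation and elongation fell at 3 mmol/L. Of 79 flagella genes, 69 were lower at 3 mmol/L, with a median log2 difference of -0.86 (camera adjusted p = 0.00213, and 0.985 with an estimated correlation). Of 68 desaturation and elongation genes, 54 were lower, with a median of -0.62 (adjusted p = 0.0452, and 0.985 with an estimated correlation). Ribosomal protein genes rose relative to other genes, with 92 of 147 higher and a median of 0.14 (adjusted p = 0.0124, and 0.985 with an estimated correlation), while their mean was -0.11. The median of all tested genes was -0.37. Low-level members of the flagella and desaturation lists were above 0 in 82.9% to 95.1% and 56.5% to 78.3% in each library. Low-level ribosomal genes were above 0 in 63.6% in both 3 mmol/L libraries and in 86.4% and 50% at 27 mmol/L.

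In the desaturation list, the omega-3 desaturase TRINITY_DN58767_c7_g2 had 385 ± 204 FPKM at 3 mmol/L and 1900 ± 871 at 27 mmol/L. A FAE1-type fragment (TRINITY_DN54572_c0_g2), of the enzymes that elongate fatty acids, was listed at 0 in both 3 mmol/L libraries and had 36.6 and 31.8 FPKM at 27 mmol/L. Phytoene desaturase (TRINITY_DN59546_c0_g1), an early enzyme of carotenoid synthesis, had 228 ± 126 and 996 ± 164, and an alternative oxidase (TRINITY_DN55273_c0_g1), which bypasses part of mitochondrial respiration, 101 ± 49.3 and 564 ± 53.2. A starch synthase-type gene (TRINITY_DN62467_c5_g1) had 180 ± 3.22 and 607 ± 50.6, and the copper-type nitrite reductase TRINITY_DN59256_c1_g1 11.0 ± 6.11 and 144 ± 25.9. An SCP-like extracellular protein (TRINITY_DN61976_c1_g2, chosen after its values were seen) had 80.4 ± 9.5 and 666 ± 106 (limma adjusted p = 0.36). The other genes of this paragraph had an adjusted p of 0.54. The list for starch metabolism (154 genes) had a median of -0.25 and an adjusted p of 0.656, and that for carotenoid and isoprenoid synthesis (124 genes) -0.34 and 0.469. Among members with a mean of at least 50 these medians were -0.6 and -0.5 (camera adjusted p = 0.19 and 0.27). The median over all genes at that level was -0.42.

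Over all genes, limma called 0 of 123022 between 3 and 27 mmol/L, with 8773 at an unadjusted p under 0.05 (1772 higher, 7001 lower) against 6151 from chance, and 0 passed adjusted over the list alone. A robust prior variance called 60 genes. Leaving out 3 mmol/L replicate 1 or 27 mmol/L replicate 2 gave 2556 and 3929, of which 2426 and 3488 had a residual SD of 0. Instead of 3 lists, 11 were called without 3 mmol/L replicate 1, 6 without 3 mmol/L replicate 2 or 27 mmol/L replicate 1, and 1 without 27 mmol/L replicate 2. The flagella call was lost without 3 mmol/L replicate 2 (median -0.60) or 27 mmol/L replicate 2 (-1.09), and the ribosomal call without 3 mmol/L replicate 2 (-0.04) or 27 mmol/L replicate 1 (0.07), with medians of 0.213 (ribosomal) and -1.288 (flagella) without 3 mmol/L replicate 1. The desaturation call was lost without 3 mmol/L replicate 1 (-0.13), 27 mmol/L replicate 2 (-0.63) or any 9 or 18 mmol/L library (-0.62 each). With centred libraries flagella (-0.12) and desaturation (0.11) were not called, and 3 lists were called up and 0 down, against 1 up and 2 down. With a mean of at least 50 only the ribosomal list was called (adjusted p = 0.000103, and 0.975 with an estimated correlation). Without the 3 libraries richest in prokaryote-type transcripts 0 lists were called (medians -0.569 for flagella, 0 for ribosomal and -1.154 for desaturation genes). With a mean of at least 50 and without those 3 libraries the desaturation list was called down (median -1.24, adjusted p = 6.58e-05, not run with an estimated correlation), with 1 library against 1 and the spread of the 9 mmol/L pair alone. Fry called 0 lists.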

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

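The alternatives with a mean of at least 50, with a pseudocount of 10, with title-only matching, with genes holding a domain hit, and without the 3 libraries richest in prokaryote-type transcripts were chosen after the data were seen, as was the comparison of 3 mmol/L with the 6 other libraries. No identifier had an isoform suffix, so counting 1 row per transcript changed nothing and was not run. Where 1 library of a pair is left out, the lone library is assumed to vary like the other groups, and without the 3 libraries this holds at 3, 18 and 27 mmol/L. Causes of the differences were not tested, except where named. Of the values under alternatives, 113 counts stayed within 1.5 times and 82 moved. For lists 164 kept their call and direction, 116 lost the call and 6 reversed. For single genes 4311 kept both, 134 changed direction without a call, 87 became called and 1 reversed, which here means a change of direction with a call. The 134 are therefore not among the reversed results given below. In the 4 nitrate comparisons no gene was called in the main fit, so there keeping both means staying uncalled in the same direction. Counts that stayed include those with no gene called in either fit. Values of 1 fragment lie between 7.57 and 10.93 FPKM at 300 bp, which limits what genes near that level can show.

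Genes called by limma were 0 in each comparison. With centred libraries 6 were called in 3 against 18 mmol/L and 5 in 3 against 27 mmol/L. With a robust prior variance 43, 4, 1 and 60 were called in 3 against 18, 9 against 18, 27 against 18 and 3 against 27 mmol/L. Without the 3 libraries richest in prokaryote-type transcripts the counts were 15506, 12119, 14052 and 13608, of which 14924, 11566, 13824 and 13323 had a residual SD of 0, being equal in the 1 pair that remains. With a mean of at least 50 as well, limma called 0 in all 4, with 4847, 397, 478 and 2790 at an unadjusted p under 0.05. Leaving out 1 library gave 0 to 2553, 0 to 2472, 0 to 4170 and 0 to 3929 genes. Of the 2553, 2472, 4170 and 3929, 2426 (without 3 mmol/L replicate 1), 2423 (without 18 mmol/L replicate 1), 3488 and 3488 (without 27 mmol/L replicate 2) had a residual SD of 0.

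Lists called were 5, 1, 4 and 3 in 3 against 18, 9 against 18, 27 against 18 and 3 against 27 mmol/L. Camera with an estimated correlation and fry called 0 in all 4. With a mean of at least 50 the counts were 1, 3, 1 and 1, and without the 3 libraries 1, 0, 1 and 0. With both, 6 (3 up and 3 down), 4 (1 up and 3 down), 2 (both up) and 2 (both down) were called, against 4 up and 1 down, 1 down, 4 up, and 1 up and 2 down. In 3 against 18 mmol/L there were 2 with a mean of at least 5, 12 with centred libraries (11 up and 1 down, against 4 up and 1 down), 8 at an E-value of at most 1e-30 and 10 with title-only matching. Among genes with a domain hit there were 7 (3 up and 4 down), without the chlorophyll and haem list (camera adjusted p = 0.0515). In 9 against 18 mmol/L there were 2 with a pseudocount of 10. In 27 against 18 mmol/L there was 1 with a pseudocount of 0.1, 1 with a mean of at least 5, 0 with centred libraries, 1 with the single best hit, 1 at an E-value of at most 1e-30 and 0 among genes with a domain hit. In 3 against 27 mmol/L there were 7 with the single best hit, 8 with a pseudocount of 10 and 5 with title-only matching. With centred libraries there were 3 (3 up and 0 down, against 1 up and 2 down). Leaving out 1 library gave 1 to 8, 0 to 2, 0 to 7 and 1 to 11 lists.

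With the replicate number as a block, limma called 0 genes in each of the 4 comparisons, and 6, 3, 5 and 7 lists. The correlations hint at shared handling by number but were not over 0.1 in every pair of groups, so the numbers are not taken to pair the libraries: deviations from the group mean correlated at 0.20 between 3 and 9 mmol/L, 0.18 between 3 and 18, 0.05 between 3 and 27, 0.20 between 9 and 18, 0.19 between 9 and 27, and 0.50 between 18 and 27.

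Results that reversed were the amino acid synthesis and glycolysis lists in 3 against 18 mmol/L, with medians of -0.321 and -0.315 at a mean of at least 50. Neither was called (camera adjusted p = 0.741 and 0.992), and the median over all genes at that level was -0.35. The amino acid list in 27 against 18 mmol/L had medians of 0 (without 27 mmol/L replicate 1) to 0.528 (without 27 mmol/L replicate 2). The flagella list had medians of -0.494 (3 against 18 mmol/L) and -0.284 (3 against 27 mmol/L) at a mean of at least 50 without the 3 libraries, where camera placed it above the other genes. Fry gave the ribosomal list in 3 against 27 mmol/L (median 0.139) the direction down. The ammonium transporter TRINITY_DN59747_c0_g1 had a log2 difference of -2.35 in 3 against 27 mmol/L without the 3 libraries, against 0.09 with them.

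For 3 mmol/L against the 6 other libraries, 165 genes were called with a mean of at least 50. With a mean of at least 1 the count was 312. In simulated data at that filter, 18% and 21% of calls were false with moderated and drawn variances. The count was 290 with a mean of at least 20 and 654 with libraries rescaled to the same total. With centred libraries it was 94 (28 higher and 66 lower, against 14 and 151). Leaving out 1 library gave 10 to 1778.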

Other observations

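The comparison of 3 mmol/L with the 6 other libraries, title-only matching and the tests of the 3 patterns weighed below were chosen after the values were seen, while the lists of other organisms were planned. Over 24485 genes with a mean of at least 50, limma called 165 genes, 14 higher and 151 lower at 3 mmol/L. In all 165, both 3 mmol/L libraries lay beyond the other 6, which choosing genes by a small p in the same libraries favours. The prior variance follows the mean log2 value over the 8 libraries. At like levels, a gene at 0 in 6 libraries has a lower mean than one at 0 in 2, so rises and falls need not be called alike. How far this shaped the counts of 14 and 151 was not tested. The median log2 difference over all 24485 genes was -0.32, and with libraries centred on the median 94 genes were called. An SCP-like extracellular protein gene (TRINITY_DN61976_c1_g2) fell from 600 ± 79.3 FPKM (SD, n = 6) to 80.4 ± 9.5 (n = 2), a log2 difference of -2.88 ± 0.28 (SE, adjusted p = 0.011). The fasciclin-domain gene TRINITY_DN54663_c0_g1 fell (log2 difference -3.43 ± 0.42, adjusted p = 0.013), as did the family 1 glycosyl hydrolase TRINITY_DN57984_c0_g1 (-2.12 ± 0.28, adjusted p = 0.017) and expansin A TRINITY_DN61315_c1_g1 (-2.28 ± 0.33, adjusted p = 0.024). The omega-3 desaturase TRINITY_DN58767_c7_g2 (-2.27 ± 0.39) and the RuBisCO activase TRINITY_DN62377_c7_g1 (-2.40 ± 0.42) also fell, both at an adjusted p of 0.043. An argonaute-like gene (TRINITY_DN62819_c0_g1), of the family that binds small RNAs, was at 107 ± 21.4 and 410 ± 108 FPKM (adjusted p = 0.048). A cytochrome c1 gene (TRINITY_DN58947_c7_g1), a subunit of respiratory complex III, rose from 1370 ± 245 to 4060 ± 483 FPKM (adjusted p = 0.042).

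Of the 165 genes, 29 had a domain hit at the E-value limit, 4 were of prokaryote type and 24 were listed at 0 in both 3 mmol/L libraries. Prokaryote type refers to the collection of the best domain model and does not show a bacterial origin. One of the 4, a hybrid cluster protein gene (TRINITY_DN58077_c1_g1), lay between 1420 and 14500 FPKM over all libraries. The ribosomal list rose (median 0.30, camera adjusted p = 2.1e-07) and the starch list fell (median -0.55, adjusted p = 0.025), and both had an adjusted p of 0.99 with an estimated correlation. The count was 10 without 27 mmol/L replicate 1, 12 without 18 mmol/L replicate 2, 16 without 9 mmol/L replicate 2, 58 without 27 mmol/L replicate 2, 73 without 3 mmol/L replicate 1, 98 without 9 mmol/L replicate 1 and 1778 without 3 mmol/L replicate 2. Not among the 165, a gene with a ribosomal protein S7 model (TRINITY_DN62371_c4_g4) was at 542 and 433 FPKM in the 3 mmol/L libraries and listed at 0 in the other 6 (limma adjusted p = 0.48 in 3 against 18 mmol/L).

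None of the 4 lists of other organisms was called in the 4 nitrate comparisons as matched. With title-only matching, bacterial markers (adjusted p = 0.0428) and retroelements and viruses (adjusted p = 0.0269) were called up in 3 against 18 mmol/L, and at an adjusted p of 0.977 with an estimated correlation neither was. As matched, the lowest adjusted p was 0.0595 for bacterial markers (193 genes, 14 also in a pathway list; 3 against 18 mmol/L) and 0.301 for animal markers (271 genes, 121 also in a pathway list; 27 against 18 mmol/L). It was 0.0819 for fungal markers (175 genes, 61 also in a pathway list) in 3 against 27 mmol/L, and 0.319 for retroelements and viruses (412 genes, 24 also in a pathway list) in 27 against 18 mmol/L.

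Lower values at 3 mmol/L are the first pattern weighed. The excess of falls over rises among the called genes is subject to the unequal prior variance given above. Lower depth of the 3 mmol/L libraries is argued against in part, since 4 libraries of other groups have a lower relative depth than both. That measure also depends on fragment length and on the scaling of libraries. As 3 mmol/L replicate 1 had the fewest genes above 0 (65183), lower depth of that library is not excluded. Prokaryote-type RNA diluting 3 mmol/L replicate 2 is argued against in part for the 151 genes called lower. Low-level prokaryote-type genes held 0.14% of the summed FPKM of that library, and also 0.14% of 27 mmol/L replicate 1. This share leaves out better expressed genes and genes without a domain hit, so it does not measure all prokaryote RNA. The genes called lower had a median log2 difference of -3.11 in 3 mmol/L replicate 1 and -2.5 in replicate 2. Choosing them by a small p favours a fall in both libraries. Without 3 mmol/L replicate 2, 1633 genes were called lower. That fit sets 1 library against 6, with no spread at 3 mmol/L, so its count cannot decide on dilution. Chance is not excluded: with a pseudocount of 0.1 and with centred libraries, 2 of the 28 splits of the 8 libraries into 2 and 6 gave as many genes, the real split giving 116 and 94 and the split of 18 mmol/L replicate 1 with 27 mmol/L replicate 1 giving 148 and 168 (165 against 149 with neither change). An effect of nitrate stays open and untested apart from these.

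The libraries 18 mmol/L replicate 1 and 27 mmol/L replicate 1 resemble each other, with an SD of the log2 difference of 0.84 against 1.40 and 1.39 within the labelled pairs. That 1 library was deposited under 2 names is argued against, since the share of low-level prokaryote-type genes above 0 differs by 33.3 percentage points. Library preparation (fragment length) stays open: these 2 libraries are the 2 lowest of 8 in the value of 1 fragment on transcripts of 210 bp against 300 bp, at ratios of 2.066 and 1.953, although 2.066 lies nearer to the 2.137 of 3 mmol/L replicate 2. Exchanged labels between 18 and 27 mmol/L cannot be told apart from shared handling of libraries with the same replicate number, since 18 mmol/L replicate 2 and 27 mmol/L replicate 2 also differ by only 1.05 and both accounts predict that. The 2 libraries are of different nitrate groups, and no biological explanation of their likeness was tested.

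Prokaryote-type transcripts were above 0 far more often in 3 mmol/L replicate 2 and 27 mmol/L replicate 1 than in the other libraries. Greater depth of 3 mmol/L replicate 2 is argued against in part, since 6 libraries detect more low-level plant-type genes. That share is also low in 3 mmol/L replicate 1 (68.8%), so it is no neutral measure of depth. Greater depth of 27 mmol/L replicate 1 is argued against as the whole cause, since it detects 33.3 percentage points more prokaryote-type genes than the library of greatest relative depth. Depth is not excluded, since 3 mmol/L replicate 2, 27 mmol/L replicate 1 and 18 mmol/L replicate 1 had the highest relative depths (0.947, 0.996 and 1.0). Their ratios of the 1-fragment value at 210 bp to 300 bp were the lowest (2.137, 1.953 and 2.066). Fragment length was not tested here. RNA of bacteria in the cultures of 3 mmol/L replicate 2 and 27 mmol/L replicate 1 stays open. These 2 libraries also detect the most low-level bacterial marker genes, at least 61.2%, although poly(A) selection depletes bacterial RNA. The rise was not confined to the bacterial list. Low-level animal markers were above 0 in 81.2% and 80.3% of cases in these 2 libraries (41% to 59.8% in the others). Fungal markers were above 0 in 63.1% and 83.1% (36.9% to 56.9%), and retroelements and viruses in 69.4% and 78.9% (39.7% to 55.2%). Matched on the model title only, these lists shrink from 271, 175 and 412 genes to 24, 4 and 190. They therefore cannot decide whether the rise is bacterial. Low-level proteasome and autophagy genes rose in these 2 libraries, to 76.3% and 89.5% (63.2% to 73.7%). Flagella genes did not, at 82.9% and 95.1% (85.4% to 95.1%). As each of the 2 has a partner of the same nitrate concentration at 17.4% and 15%, nitrate alone does not account for the pattern, and other biological reasons were not tested.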
